A study of Homo sapiens and Mus musculus with 136 samples.

How the data were processed

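The series holds 136 samples from adrenal material. Of these, 20 are RNA-seq libraries of adrenal glands from C57BL/6 mice labelled p15, 10 labelled wild type (WT) and 10 labelled knockout (KO) for ZFP36L2. The others are from H295R, a human adrenocortical carcinoma cell line: 45 of total RNA, 15 of RNA labelled with 4-thiouridine for 20 minutes, 18 of ribosome footprints and 38 of small RNA. The cells were left untreated or were given 100 nM angiotensin or 10 µM forskolin. Groups, replicate numbers, preparation batches and sequencing lanes were taken from the labels alone.

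The submitters' processing notes name Bowtie 1.0.1, RSEM 1.2.11 and the builds hg38 and mm10, with no role or order. How each file was counted, filtered or normalized is not given in the sources used here. The mouse file was deposited as whole-number counts for 39176 Ensembl gene IDs, of which 4979 had no count in any library. Totals ran from 14424174 to 41057533 counts per library. Whole numbers do not exclude estimated counts that were rounded before deposit. Genes that share sequence with a near copy can have been counted for either one.

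The H295R file holds 17336 transcript IDs and 78 columns. In 24 of them the deposited values are log10 values: 10 raised to the value gave a whole number of hundredths in 100% of the values under 10 (tolerance 0.001 hundredths), and the sums over transcripts on the linear scale lay between 240895 and 576950. The unit on the linear scale is not named, so depth is unknown and no interval from counts is given. The other 54 columns, and all 38 columns of the small RNA file, hold deposited values of unknown unit that were checked and used in no comparison, for the reasons given with the results. This leaves 44 samples in use and 92 not used.

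Mouse counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test with robust estimation). The model had genotype and the spike-in set, since 5 KO and 5 WT libraries carry a spike-in label and 5 of each do not. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Standard errors are the absolute log2 fold change divided by the square root of F. Each set of 10 libraries was also fitted alone, and the difference in KO effect between sets was tested as an interaction. Single library measures were compared by two-sided permutation tests with 100000 resamples over all 20 libraries and by exact permutation tests within each set.

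The H295R comparisons had been planned for counts. As the usable columns hold log values, limma 3.58.1 was used on the values in log2, centred on each column's median, for transcripts with a mean log10 value of at least 0. The 18 columns of the 9 groups with usable values in both labelled replicates entered 1 model with group and preparation batch. F tests covered 0.25, 0.5, 1 and 2 h of angiotensin against untreated, of forskolin against untreated, and of angiotensin against forskolin at the same time. At 4, 8 and 24 h 1 column per group was usable, and no test was made.

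Both models were tested on simulated data with 200 changed features. For the mouse comparison, with 15420 simulated genes tested, 48 of 81 changes of 1.5-fold, 49 of 59 of 2-fold and 56 of 58 of 4-fold were called, and 1.3% of the calls were false. These simulated counts had no difference between spike-in sets and no spread shared by the genes of a library. The real libraries differed between the sets, so these rates need not hold for the real calls. For angiotensin against untreated in H295R, with 15344 transcripts tested, 0 of 76 changes of 2-fold, 21 of 63 of 4-fold and 40 of 53 of 8-fold at every time were called, with 1 false call. For angiotensin against forskolin the same changes gave 15 of 76, 50 of 63 and 49 of 53. The simulated H295R noise was independent between transcripts. Its SD was taken over the columns of a batch before centring, so differences between columns and treatments were part of it. These rates too need not hold for the real columns.

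The IDs named in the text follow part of a rule fixed before the data were examined. This part asked for an adjusted p under 0.05 and a group mean of at least 10 CPM (counts scaled to the same total in each library). It also asked for the same sign in both spike-in sets, with IDs ranked by fold change. Below, the rule means this part. The full rule asked for a gene symbol too, and for 10 IDs each way. Neither the files nor the name tables used here pair the mouse gene IDs or the human transcript IDs with symbols. The symbol was therefore dropped, and 2 IDs each way are given in place of 10. Without symbols, the gene lists fixed beforehand, the knocked-out gene itself and its family were not analysed here.

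Alternatives fixed before the data were examined were another scaling, no filter, DESeq2 1.42.0, a fold threshold, other terms for batch, subsets of the mouse libraries and leaving out each library. Other choices were added afterwards and are named as such with their results. The sequencing lane is a labelled batch shared by libraries of both genotypes and sets, and was used as a block in an alternative. Of the 10 pairs of libraries of 1 genotype in the same lane, 8 had deviations that correlated above 0 (median r 0.107, range -0.35 to 0.26), against a median r of -0.066 over 40 pairs across sets in other lanes. With the lanes reassigned in all 14400 ways, a mean r as high came up with a one-sided exact permutation p of 0.148, in a test chosen after the values were seen. For WT and KO libraries of 1 lane and set, 4 of 10 pairs had an r over 0.1, those of lanes 3 and 4 in both sets (r of 0.23 and 0.31 unspiked, 0.45 and 0.44 spiked), and 4 had an r under -0.1. Whether lanes pair the libraries was left open, and blocked values are given where they change a call. No replicate pair agreed within sampling noise: the lowest chi-square per degree of freedom between mouse libraries of 1 genotype was 20.6. The labels do not say that libraries came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Checks and figures used Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9.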

Results

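RNA was measured in mouse adrenal glands labelled WT or KO for ZFP36L2, an RNA-binding protein that promotes the decay of mRNAs with AU-rich elements. It was also measured in H295R cells, a human adrenocortical line that makes steroids. The cells had been treated with angiotensin, a peptide hormone that drives aldosterone production, or forskolin, which activates adenylyl cyclase and so raises cAMP. The mouse comparison had 10 KO and 10 WT libraries of 14424174 to 41057533 counts. Pearson's r of log2(count + 1) between libraries of 1 genotype was 0.968 to 0.991 over gene IDs. In H295R, 9 groups of 2 columns could be compared.

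The mouse comparison asks which adrenal transcripts differ between glands labelled KO and WT for ZFP36L2. The gene ID ENSMUSG00000045999.8 rose the most of all called genes: it was at 0.826 ± 0.186 CPM in WT and 86.9 ± 34.4 CPM in KO libraries (SD, n = 10 each), a log2 fold change of 6.92 (SE 0.30, edgeR adjusted p = 1.03e-11). All 10 KO libraries, at 41.1 to 143 CPM, lay above the highest WT library, at 1.19 CPM. The rise was 6.94 on the log2 scale in the unspiked set (edgeR adjusted p = 0.000323) and 6.86 in the spiked set (edgeR adjusted p = 1.50e-06). In every library the ID was counted at least 18 times.

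ENSMUSG00000076258.1 had the next largest rise among the IDs that met the rule, with a log2 fold change of 3.31 (SE 0.96, edgeR adjusted p = 0.0441). It averaged 2.45 ± 0.860 CPM in WT and 36.7 ± 81.3 CPM in KO libraries (SD, n = 10 each). This spread came from KO library 5 at 260.4 CPM and KO library 4 at 70.0 CPM, against 1.43 to 9.45 CPM in the other 8. Of the 10 KO libraries, 6 lay above the highest WT library and 1 lay below the lowest. Without KO library 5 the log2 fold change was 2.17 (edgeR adjusted p = 0.0489). In the unspiked and spiked sets alone it was 5.20 and 1.27 and passed the test in neither (edgeR adjusted p = 0.546 and 0.133), and leaving out 1 library ended its call in 11 of 20 cases. With the sequencing lane as a block its log2 fold change was 2.30 and the call was lost (edgeR adjusted p = 0.0887).

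ENSMUSG00000032487.7 fell by 1.88 on the log2 scale (SE 0.56, edgeR adjusted p = 0.0491), the largest fall among the IDs that met the rule. It averaged 17.9 ± 13.3 CPM in WT and 4.71 ± 4.74 CPM in KO libraries (SD, n = 10 each), and 5 of 10 KO libraries lay below the lowest WT library. The WT libraries themselves ranged from 2.96 to 37.8 CPM. ENSMUSG00000034765.6 fell by 0.98 (SE 0.28, edgeR adjusted p = 0.0411), from 19.0 ± 10.3 CPM in WT to 8.35 ± 2.58 CPM in KO libraries (SD, n = 10 each). Again 5 of 10 KO libraries lay below the lowest WT library. Neither ID passed the test within a set: the log2 fold changes of ENSMUSG00000032487.7 were -2.77 and -1.16, and those of ENSMUSG00000034765.6 were -1.33 and -0.67, in the unspiked and spiked sets. Leaving out 1 library ended the call of ENSMUSG00000032487.7 in 16 of 20 cases and that of ENSMUSG00000034765.6 in 12 of 20. With the sequencing lane as a block both calls were lost (log2 fold changes -1.77 and -0.93, edgeR adjusted p = 0.0567 and 0.0645).

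**Figure D1:**
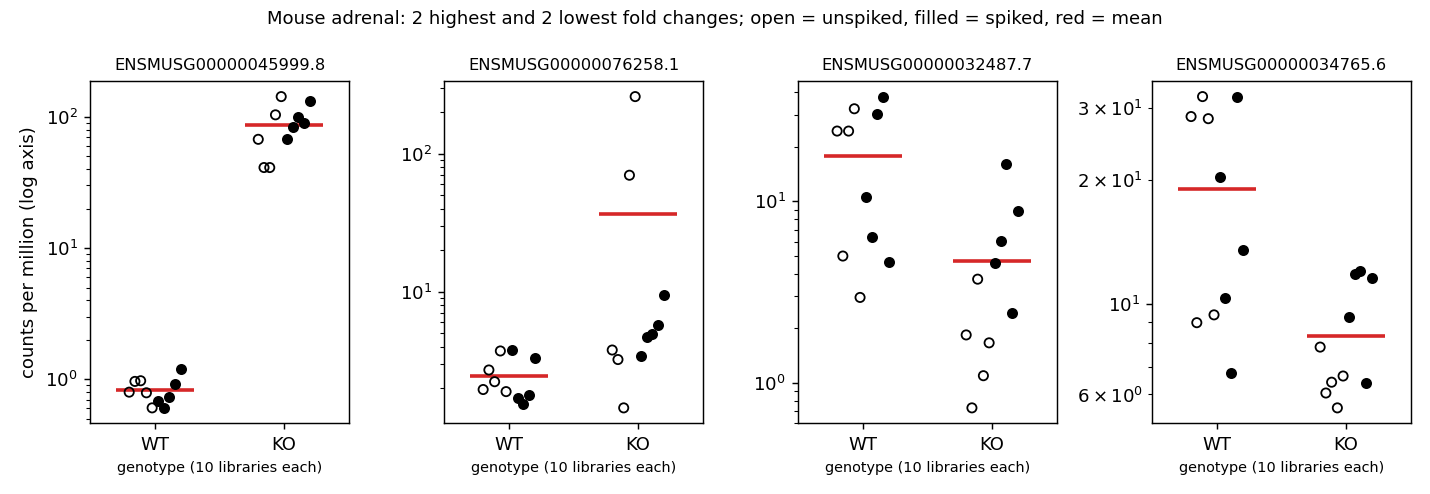
CPM (log axis) of the 4 named gene IDs in 10 WT and 10 KO mouse libraries, with open points for unspiked and filled points for spiked libraries and a red line at the mean. ENSMUSG00000045999.8 separated every KO from every WT library, while the other 3 IDs overlapped between genotypes.

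Across all 15546 genes tested, 674 were higher and 333 lower in KO libraries at an adjusted p under 0.05 with edgeR. Most changes were small: the median absolute log2 fold change of the 1007 called genes was 0.50, 632 of them changed by less than 1.5-fold, and 48 changed by at least 2-fold, of which 42 were higher in KO. The common biological coefficient of variation was 25%. Within each spike-in set of 5 KO and 5 WT libraries, edgeR called 1 gene, ENSMUSG00000045999.8 in both. An unadjusted p under 0.05 was found for 1378 of 15525 genes in the unspiked and 2815 of 15649 in the spiked set. In the fit of all libraries 3861 of 15546 genes had one, where chance gives 777. No gene passed the test for a difference in KO effect between the sets (0 of 15546 with edgeR, 513 at an unadjusted p under 0.05, where chance gives 777). Fold changes of the sets correlated across 15289 genes with r = 0.50, where genes are not independent replicates, and 70.9% had the same sign in both. The count of called genes depended on single libraries, from 209 without KO library 9 to 1575 without KO library 1, and on the test, with 1746 from DESeq2. Without KO libraries 3 and 5, in which ENSMUSG00000075014.1 took over 30% of counts, 94 genes were called. All these fits took the libraries as independent, which the labels do not state. With the libraries of 1 genotype and lane summed, edgeR called 1 gene, ENSMUSG00000045999.8.

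KO libraries were shallower than WT libraries, at 23780035 ± 4867146 against 31469469 ± 4039848 counts (SD, n = 10 each, permutation test p = 0.00026, adjusted p = 0.00104 over 4 library measures). The difference, KO minus WT, was -10175228 counts in the unspiked set (n = 5 each, exact permutation test p = 0.00794) and -5203640 counts in the spiked set (n = 5 each, exact permutation test p = 0.0317). These tests were two-sided. The number of gene IDs with a count did not differ beyond the spread, at 23008 ± 1859 in KO and 22636 ± 1037 in WT libraries (SD, n = 10 each, permutation test p = 0.591, adjusted p = 0.591). Among the most abundant gene IDs, ENSMUSG00000075014.1, singled out after its values were seen, ranged most widely. It took 36.2% of all counts in KO library 3 and 40.1% in KO library 5, and at most 8.16% in any other library. Its mean share was 8.87 ± 15.6% in KO and 1.04 ± 1.14% in WT libraries (SD, n = 10 each, permutation test p = 0.169, adjusted p = 0.338). The most abundant gene ID took 23.5 ± 9.30% of counts in KO and 26.7 ± 5.72% in WT libraries (permutation test p = 0.385, adjusted p = 0.513), and within the unspiked set 16.8 ± 7.49% against 23.7 ± 1.34% (n = 5 each, exact permutation test p = 0.00794). Within the spiked set it took 30.3 ± 4.83% in KO and 29.8 ± 6.96% in WT libraries (n = 5 each, exact permutation test p = 0.857).

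**Figure D2:**
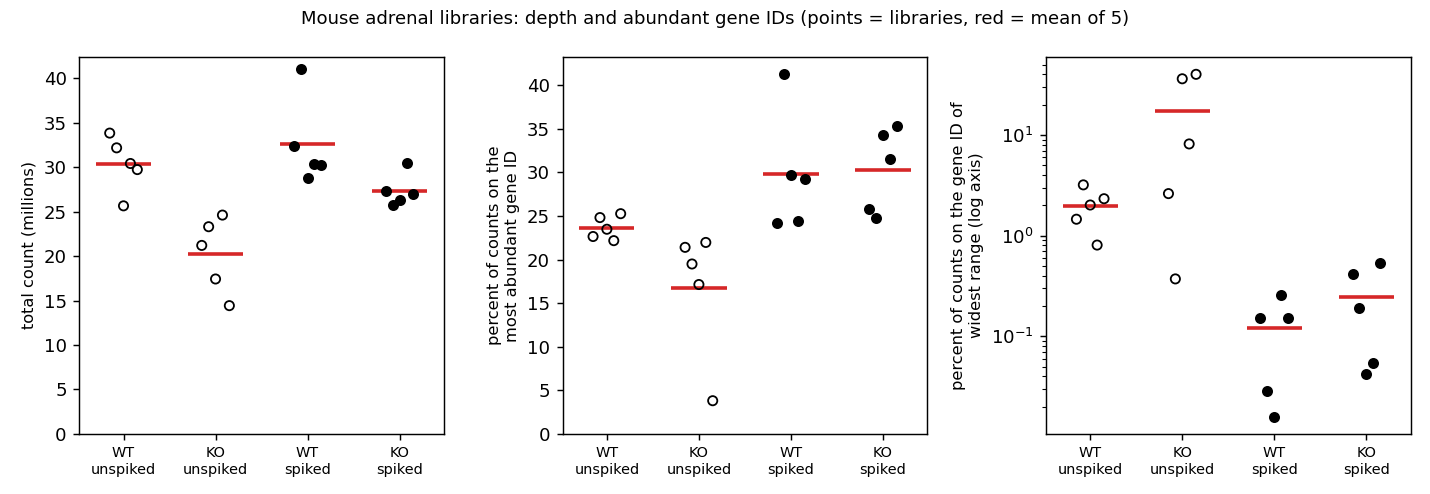
Total counts (drawn in units of 1e6), percent of counts on the most abundant gene ID, and percent on the gene ID of widest range (log axis) in mouse libraries by genotype and spike-in set, with points for libraries and a red line at the mean of 5. KO libraries were shallower in both sets, and the gene ID of widest range reached 36.2% and 40.1% in 2 unspiked KO libraries.

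In H295R the comparisons ask which transcripts respond to angiotensin and to forskolin, and where the responses differ. Over 0.25 to 2 h no transcript was called with limma, of 15448 tested in 18 columns. For angiotensin against untreated, 0 were called at an adjusted p under 0.05 (lowest limma adjusted p = 0.978) and 469 had an unadjusted p under 0.05. For forskolin against untreated, 0 were called (lowest limma adjusted p = 0.569) and 582 had an unadjusted p under 0.05. For angiotensin against forskolin, 0 were called (lowest limma adjusted p = 1.00) and 239 had an unadjusted p under 0.05, where chance gives 772 in each comparison. Each of the 4 times alone also gave 0 calls in each comparison. At 0.25, 0.5, 1 and 2 h alone, 963, 364, 832 and 810 transcripts for angiotensin had an unadjusted limma p under 0.05. For forskolin these were 924, 1024, 497 and 774, and between the treatments 564, 662, 358 and 371, where chance gives 772 each. With simulated changes at every angiotensin time the same model called 75.5% of 8-fold and 0% of 2-fold changes against untreated. Against forskolin 19.7% of the same 2-fold changes were called. The simulated noise was independent between transcripts, so these rates need not hold for the real columns. Real 2-fold responses may have been missed. Leaving out 1 column gave up to 64 calls for angiotensin, without its replicate 2 at 0.25 h, and up to 225 for forskolin and 123 between the treatments, both without forskolin replicate 2 at 0.5 h.

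In each of these groups replicate 1 carries the label of the first preparation batch and replicate 2 that of the second. Labelled replicates correlated over transcripts with r from 0.655 to 0.781, a spread that cannot be told apart from the batch difference. The 24 usable columns formed 2 blocks of 12. Within the first block r was 0.803 to 0.915, within the last 0.957 to 0.977, and between them 0.652 to 0.787. Mean log10 values were 1.01 to 1.14 in the first block and 0.221 to 0.455 in the last. All columns of the first block carry the label of the first preparation batch, and the last block holds 3 columns of that batch and 9 of the second. Those 3 columns belong to none of the groups compared. After each batch's mean was taken out, columns with the same label correlated with a mean r of 0.012 and other pairs with a mean r of -0.002, and 1 of 9 labels correlated best with its own (one-sided exact permutation test over all 362880 pairings, p = 0.329). Groups are given as labelled, and 0 calls do not show that the treatments had no effect.

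**Figure D3:**
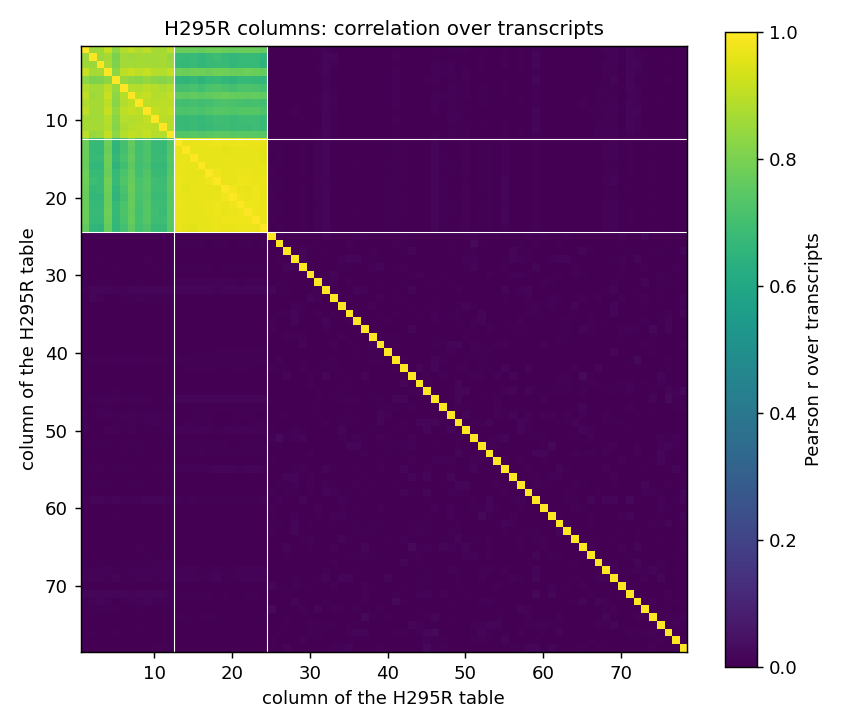
Pearson's r over transcripts (colour, values under 0 drawn as 0) between all 78 columns of the H295R table in file order, with white lines after columns 12 and 24. The first 24 columns form 2 blocks of 12, and the other 54 correlate with no column but themselves (absolute r of at most 0.027).

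No comparison was made from the other 54 H295R columns, which by their labels are all of the 4-thiouridine and footprint samples, the total RNA of the later experiments and 6 columns of the angiotensin and forskolin time course. Their values correlated with no other column over 17336 transcripts (highest absolute r 0.027), and 25 labelled replicate pairs among them had r from -0.014 to 0.013. Column means lay between 1.04 and 1.06 and SDs between 0.566 and 0.579. The 38 small RNA columns held whole numbers of which 95.6% lay under 10000, and 48.5% of those under 5000. Their 39 labelled replicate pairs had r from -0.042 to 0.064 on the log2 scale, and hsa-let-7a-5p ranged from 559 to 13773. The planned comparisons of labelled RNA, translation and miRNAs are therefore not reported.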

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

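The tests below were chosen after the results were seen, except the tests that leave out every pair of KO libraries and that split the libraries with lane pairs kept together, whose possible outcomes were written down beforehand. The number of splits with lane pairs kept together was raised from 60 to 100 after a first result was seen.

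Of 16 checks for a sample far from the others of its group, 4 found one. In 100000 simulated groups of 10 independent normal values the same rule found one in 4.96%, about 1 in 20, but these checks share libraries and CPM values need not be normal. WT library 7 had the highest total of the WT libraries, 41057533 counts against 33845489 in the next. The same library had 41.4% of its counts on the most abundant gene ID, against 29.7% in the next. KO library 5 had 260.4 CPM of ENSMUSG00000076258.1, against 70.0 CPM in the next KO library. KO library 8 had 16.1 CPM of ENSMUSG00000032487.7, against 8.85 CPM in the next.

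In the mouse comparison 1007 genes were called with 20 libraries and 1 within each set of 10. In 60 splits of the 20 libraries 1, the real one, gave as many genes, and the highest of the others gave 2. These splits were drawn without regard to the spike-in set, while the real one holds 5 libraries of each genotype in each set. They therefore do not exclude chance for the whole count. With the libraries of 1 genotype and lane kept together, 1 of 100 splits, the real one, gave as many, but a split that exchanged WT lane 5 and KO lane 1 gave 959, and summing those libraries left 1 gene called, so the size of the count is weak evidence where such libraries are not independent. Leaving out KO libraries 3 and 5, in which ENSMUSG00000075014.1 took over 30% of counts, left 94 genes. Of the 45 pairs of KO libraries 10, that pair included, left as few. Some of these pairs include KO library 3 or 5, but KO libraries 8 and 9 left out together left 1 gene. The calls therefore do not rest on KO libraries 3 and 5 alone. A part for the most abundant gene ID is not excluded. It took 34.3%, 31.6% and 35.3% of counts in KO libraries 8, 9 and 10. In the spiked set its mean was 30.3% in KO and 29.8% in WT libraries (exact permutation test p = 0.857). Fewer libraries may account for the loss within a set, as 20 draws of 5 KO and 5 WT libraries that mixed both sets called a median of 1 gene and at most 1830, and a difference in ZFP36L2 effect between sets stays open, with 0 genes called by the interaction.

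A further pattern is that 54 H295R columns share no signal with any other column. Rows in another order are argued against, because at most 0.335% of the low values of such a column lay on the grid of hundredths that held all low values of the other 24. Low sequencing depth is argued against, because at least 99.99% of the values of each column were unique. The values are consistent with independent draws: the spread over transcripts of their mean was 1.005 times that of independent columns. How they came to be so was not tested, nor was any biological explanation.

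The last pattern is that the 24 usable H295R columns split into blocks that differ from the labels. The preparation batch as labelled is argued against, because its 3 columns in the last block reached an r of at most 0.782 with the rest of their batch and at least 0.957 with the other batch. Sequencing lane is argued against, because all 5 lanes held columns of both blocks. Column names out of step with the values are a candidate explanation that was not tested for these 3 columns. The exact permutation p of 0.329 for columns of 1 label deviating together cannot decide it. That test held only the 18 columns of the groups compared, without these 3, and batch means were taken out first. For those 18 columns, a treatment effect too small to detect would give the same result and stays open. No columns were reassigned.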

How the results depend on the processing

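The direction of all 4 named mouse gene IDs held in all 31 alternatives. The naming rule asked for the same sign in both spike-in sets, and the fold threshold reuses the main fit. In these alternatives the direction was therefore fixed beforehand. ENSMUSG00000045999.8 kept its call in all 31 (log2 fold change 6.69 to 7.02, highest adjusted p 0.000323). The call was lost in 17 of 31 for ENSMUSG00000076258.1, 23 of 31 for ENSMUSG00000032487.7 and 19 of 31 for ENSMUSG00000034765.6, whose adjusted p ranged from 0.00137, 0.0106 and 0.00713 to 0.546, apart from the fold threshold, which ended the call of ENSMUSG00000034765.6 by its size. The 1007 mouse genes became 326 without a filter (292 shared), 1746 with DESeq2 (1005 shared), and 48 with an absolute log2 fold change of at least 1. They became 1 in the spiked set, 1 in the unspiked set and 1 with the libraries of 1 genotype and lane summed. Each set alone has fewer libraries. Summing loses independent samples only if libraries of 1 genotype and lane are independent, which was left open. Chosen after seeing the data, leaving out KO libraries 3 and 5, in which ENSMUSG00000075014.1 took over 30% of counts, gave 94, and thinning every library to the lowest total gave 863 (768 shared). DESeq2 size factors gave 1019 and no spike-in term 680. The replicate block by lane gave 1045 genes (875 shared) and ended the calls of those 3 IDs (adjusted p 0.0887, 0.0567 and 0.0645), while ENSMUSG00000045999.8 kept its call (7.19e-12). Leaving out 1 library gave 209 to 1575: 664, 537, 425, 460 and 625 without WT libraries 1, 3, 4, 7 and 8, and 1575, 606, 1551, 494, 275, 209 and 518 without KO libraries 1, 3, 4, 5, 8, 9 and 10. The cause was not tested.

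In H295R no filter, a fold threshold, no replicate block (preparation batch left out) and, chosen after seeing the data, quantile normalization, no centring and a pseudocount of 1 all gave 0 calls in the 3 comparisons. The fold threshold reuses the main fit and can only remove calls, so its 0 was fixed beforehand. Leaving out 1 column gave 0 to 64 for angiotensin (64, 2, 3 and 12 without replicate 2 at 0.25, 0.5, 1 and 2 h, and 4 without either untreated column). It gave 0 to 225 for forskolin (51, 225, 6 and 7 without replicate 2 at those times, 1 without replicate 1 at 0.25 h, and 4 and 7 without untreated replicates 1 and 2). It gave 0 to 123 between the treatments (21, 1, 3 and 1 without angiotensin replicate 2, and 27, 123, 1 and 3 without forskolin replicate 2). The lone column is then assumed to vary like the other groups, and the cause was not tested. ERCC scaling was not run, as the tables used here hold 0 spike-in rows, nor were the gene list tests, DESeq2 and its size factors on log values, or the alternatives of the comparisons not made. Unknown depth in H295R limits what can be said of low values.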

Other observations

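The tests of shares of counts in this part were chosen after the values were seen. The share of ENSMUSG00000075014.1 differed between the spike-in sets. It took 9.72 ± 15.2% of counts in unspiked and 0.185 ± 0.175% in spiked libraries (SD, n = 10 each, permutation test p = 2e-05, the smallest 100000 resamples can give). KO libraries 3 and 5, at 36.2% and 40.1%, carried much of the unspiked mean. On the log10 scale the share differed by 1.49, unspiked minus spiked (permutation test p = 2e-05). The difference held within WT libraries, at 1.96 ± 0.902% against 0.121 ± 0.10% (n = 5 each, exact permutation test p = 0.00794), and within KO libraries, at 17.5 ± 19.1% against 0.249 ± 0.221% (n = 5 each, exact permutation test p = 0.0238). Between the sets, with genotype in the model, edgeR called 443 genes higher and 493 lower in spiked than in unspiked libraries. The first and second principal components of the mouse libraries held 22.2% and 17.8% of the variance. Leaving out KO libraries 8 and 9 together left 1 mouse gene called, and over all 45 pairs of KO libraries the count ran from 1 to 2105.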
